A study of Homo sapiens with 12 samples.

How the data were processed

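The series holds 12 single-colour oligonucleotide arrays of 22283 probe sets, run on total RNA of the breast cancer cell lines MCF-7, T47-D and BT-474, each cultured without estrogen or with estrogen for 24 h. Each of the 6 groups has 2 arrays, which the labels' design text calls biological duplicates, so n = 2 per group. The deposited table gives 1 value per probe set and array, and these values are on a log2 scale, which was inferred from their range and spread because neither the scale nor the normalization method is given in the sources used here. Array medians differed by at most 0.0834, within the rule of 0.5 set beforehand, so the deposited log2 values were used as they are. The table has 0 columns of other samples.

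The 68 control probe sets were left out, as were the 25 percent of probe sets with the lowest mean log2 signal over all arrays (below 5.78), which left 16661 probe sets. Of all probe sets 19071 carry 1 gene symbol, 1043 several and 2169 none. Of the former, 19059 were matched to current symbols by gene identifier, which changed 0 symbols. A gene is represented by the brightest of its probe sets with 1 symbol (11963 genes, 9905 of them tested). Probe sets can bind transcripts of related genes, and no genome was at hand to test this.

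A linear model with 6 group means was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and an intensity trend, and 6 residual degrees of freedom. Contrasts were the estrogen effect in each line, its average over the 3 lines, its difference between lines (moderated F and each pair) and the 3 line differences averaged over both estrogen states. P values were adjusted by the Benjamini-Hochberg method over all probe sets tested, with 0.05 as the threshold. Errors are the moderated standard errors of the contrasts. Gene lists were tested with limma's camera on 1 probe set per gene, with a preset correlation of 0.01 and with an estimated one. Camera p values were adjusted over the lists and contrasts of each family.

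The 15 process lists were classical estrogen-induced genes, classical estrogen-repressed genes, DNA replication, mitosis, cell cycle brakes and quiescence, ribosome biogenesis, cholesterol synthesis, endoplasmic reticulum stress and chaperones, interferon response, hypoxia and glycolysis, immediate early genes, receptor tyrosine kinases and ligands, nuclear receptor coregulators, luminal epithelial identity and the 17q12 region around ERBB2. The 4 lists of other cell types were basal or mesenchymal, fibroblast, leukocyte and endothelial. The groups, contrasts, lists, naming rule and alternatives were written before the data were examined, except the actin covariate and 2 added lists, histones and amino acid synthesis with transfer RNA charging. Named genes are, for the average, the 12 largest rises and 12 largest falls among called genes with one sign in all 3 lines. For each line they are the 10 largest each way among called genes with both estrogen arrays on the same side of both control arrays. For the difference they are the 10 with the smallest F p, and for each pair of lines the 5 largest each way. Further named genes are 2 to 4 members per list with the smallest p, and always GREB1, TFF1, PGR, ESR1, MYC, CCND1, GATA3, FOXA1 and ERBB2. AREG has no probe set with 1 symbol and was not measured.

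Alternatives were quantile scaling, median centring, no filter, a filter of the lowest 50 percent, no intensity trend, each line's own 4 arrays, a replicate block, each array left out in turn, the average over 2 lines, the line differences in 1 estrogen state, the estimated correlation and the mean of a gene's probe sets. With an array left out, the lone array of its group is assumed to vary like the other groups. The alternatives on a pseudocount do not apply to log2 values.

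The scripts were tested on simulated data with the real line means and 200 of 16661 probe sets changed. Each probe set had the same spread in all groups, so the wider spread of the BT-474 control pair was not simulated. The percentage for BT-474 may therefore be too high. Of changes of 1 on the log2 scale, 80.6% were called in MCF-7, 79.1% in T47-D, 83.6% in BT-474 and 98.5% for the average, and of changes of 0.5, 26.9%, 17.9%, 22.4% and 76.1%, with 6 to 14 false calls per contrast. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.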

Results

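Total RNA from MCF-7, T47-D and BT-474 cells, established human breast cancer lines that carry the estrogen receptor, was hybridised to 12 single-colour oligonucleotide arrays. Each line was cultured either without estrogen or with estrogen for 24 h, and each of the 6 resulting groups held 2 arrays, which the series' design text calls biological duplicates. The estrogen dose and the basal medium are not given in the sources used here. Array medians lay between 6.94 and 7.02 on the log2 scale, and 2 arrays per group limit the precision of every value. Arrays of one line correlated at 0.973 or more across probe sets, and arrays of different lines at 0.904 or less. The first 2 principal components, with 48.0% and 37.1% of the variance, parted the lines, while the third, with 4.90%, set the arrays apart by estrogen state. Control replicate 2 of BT-474 lay between the states on that axis, at -0.09 against 14.2 for control replicate 1.

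On average over the 3 lines, estrogen raised receptor targets together with genes of DNA synthesis and cell division, and lowered a smaller set that included ERBB2. The largest average rises among genes with one sign in all 3 lines were those of MYBL1, a MYB-family transcription factor (log2 change 2.33 ± 0.09 SE, 5.02-fold), GREB1, an estrogen-responsive growth regulator (2.24 ± 0.10, 4.73-fold), and MYC, a transcription factor that drives growth (1.75 ± 0.10, 3.37-fold). They were followed by the secreted glycoprotein OLFM1 (1.73), the neuropeptide Y receptor NPY1R (1.58), the peroxisomal oxidase ACOX2 (1.56), the trefoil peptide TFF1 (1.44) and the progesterone receptor PGR (1.42). Asparagine synthetase ASNS rose by 1.35, the chemokine CXCL12 by 1.34, the small heat shock protein HSPB8 by 1.31 and MYB by 1.18. For MYBL1, NPY1R and PGR the signal without estrogen lay under the filter level of 5.78 in 1 or more lines, so their averages may be too small. Among the same genes the falls were led by the immune checkpoint ligand VTCN1, which fell by 1.21 on the log2 scale (2.31-fold), the homeodomain protein HOPX (-1.08), the interleukin receptor IL1R1 (-0.98), the ephrin ligand EFNA1 (-0.95) and the hypoxia-inducible transcription factor EPAS1 (-0.90). The histone transcripts H2AC6 (-0.89) and H4C8 (-0.88), the adaptor BLNK (-0.85), the receptor tyrosine kinase ERBB2 (-0.81), the sialyltransferase ST6GAL1 (-0.80), SH3BP4 (-0.76) and the growth inhibitor DDIT4 (-0.75) completed the 12 largest falls. In all, 1558 of 16661 probe sets passed limma's test at an adjusted p below 0.05, 1076 of them higher and 482 lower with estrogen, and they stood for 717 genes that rose and 302 that fell.

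Of the 31 measured members of the list of classical estrogen-induced genes, 22 rose on average and 9 did not pass, with 26 rises adjusted over the list alone. Cyclin D1 (CCND1) was among those that did not pass (0.21, adjusted p = 0.227), though it passed without T47-D estrogen replicate 2 (adjusted p = 0.0459). Of 15 classical estrogen-repressed genes, 6 fell on average, 7 adjusted over the list alone, among them EFNA1, BLNK, CCNG2 (-0.58) and ERBB2, and ESR1, which encodes the estrogen receptor itself, did not pass (-0.04, adjusted p = 0.818). DNA replication genes rose in 32 of 39 cases, 37 adjusted over the list alone, with the replication initiation factor MCM10 at 0.77, the primase-associated polymerase POLA1 at 0.68 and the helicase subunit MCM7 at 0.58. Mitotic genes rose in 39 of 43 cases, all 43 adjusted over the list alone, with the spindle checkpoint gene MAD2L1 at 0.84, the kinetochore motor CENPE at 0.60 and cyclin A (CCNA2) at 0.60. Of 23 ribosome biogenesis genes 11 rose, 14 adjusted over the list alone, the helicase DDX21 (0.75) and NOP16 (0.67) among them. These 5 lists passed limma's camera test for the average effect with the preset and with an estimated correlation between genes, the largest estimated-correlation adjusted p among them being 0.0207 for the repressed list. The test also called the list of endoplasmic reticulum stress and chaperones upward (adjusted p = 0.00524) and the interferon response list downward (adjusted p = 0.0135), with an adjusted p = 0.0960 and an adjusted p = 0.268 with an estimated correlation. ASNS and ATF4 (0.36) were the 2 risers of 18 in the former list, which gained 8 rises and 1 fall adjusted over the list alone. IRF9 (-0.35) and MX1 (-0.29) were the 2 genes that fell of 17 in the latter list, also when adjusted over the list alone. Without 1 or more single arrays or lines ATF4, IRF9 and MX1 no longer passed (highest adjusted p 0.425, 0.238 and 0.625).

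The other lists did not pass for the average effect. Of 19 luminal epithelial genes 5 fell, 6 adjusted over the list alone with 3 rises, and the 5 included ELF3 (-0.66), KRT7 (-0.63), CLDN4 (-0.48) and MUC1 (-0.46), while GATA3 (-0.23, adjusted p = 0.0519) and FOXA1 (-0.20, adjusted p = 0.223) did not pass. Among the cell cycle brakes CCNG2 and CITED2 (-0.53) fell of 16, with 1 rise and 2 falls adjusted over the list alone, and the camera adjusted p was 0.135. Of 19 hypoxia and glycolysis genes PFKFB3 rose (0.65) and NDRG1 (-0.63) and DDIT4 fell, and of 17 immediate early genes MYC, EGR3 (0.90) and KLF10 (0.85) rose and DUSP1 fell (-0.62). Among 18 receptor tyrosine kinases and ligands IRS1 (0.95) and IGF1R (0.48) rose while ERBB2 and ERBB3 (-0.44) fell. The nuclear receptor corepressor NRIP1 rose by 1.03 and CITED2 fell among 13 coregulators, ACAT2 rose (0.36) among 15 cholesterol synthesis genes, and of 14 genes in the 17q12 region around ERBB2, RARA (0.75) and TOP2A (0.63) rose and 3 fell, among them ERBB2 and PGAP3 (-0.34). Adjusted over each list alone, these 5 lists gave 4 rises and 3 falls, 4 and 4, 2 and 2, 1 and 2, and 1 rise, in the order named, and the 17q12 list 2 rises and 4 falls. Marker lists of basal or mesenchymal cells, fibroblasts, leukocytes and endothelium did not pass, the lowest adjusted p being 0.118 for the basal list. Within the tests for 15 lists and 4 contrasts, 28 of 60 passed, and 18 passed with an estimated correlation. The average count was 2429 without BT-474 control replicate 2, 964 and 1018 without BT-474 estrogen replicates 1 and 2, 998 without MCF-7 control replicate 1, and 1030 and 896 without MCF-7 estrogen replicates 1 and 2. It was 1455 over MCF-7 and T47-D alone, 672 over T47-D and BT-474 alone and 647 over MCF-7 and BT-474 alone. In the latter pairs HOPX and ERBB2 respectively no longer passed (adjusted p 0.0967 and 0.0704). The average for EGR3 rests on MCF-7, since over T47-D and BT-474 alone it was 0.01 (adjusted p = 0.953). With 1 or another line left out PFKFB3, MUC1, DUSP1, ERBB3, KRT7, IGF1R and ELF3 no longer passed either (highest adjusted p 0.402, 0.220, 0.174, 0.120, 0.0833, 0.0802 and 0.0524). GATA3 passed under several alternatives, among them quantile scaling (adjusted p = 0.0121). Without 1 or more single arrays or lines ACAT2, PGAP3 and CITED2 no longer passed (highest adjusted p 0.223, 0.152 and 0.328).

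**Figure D1:**
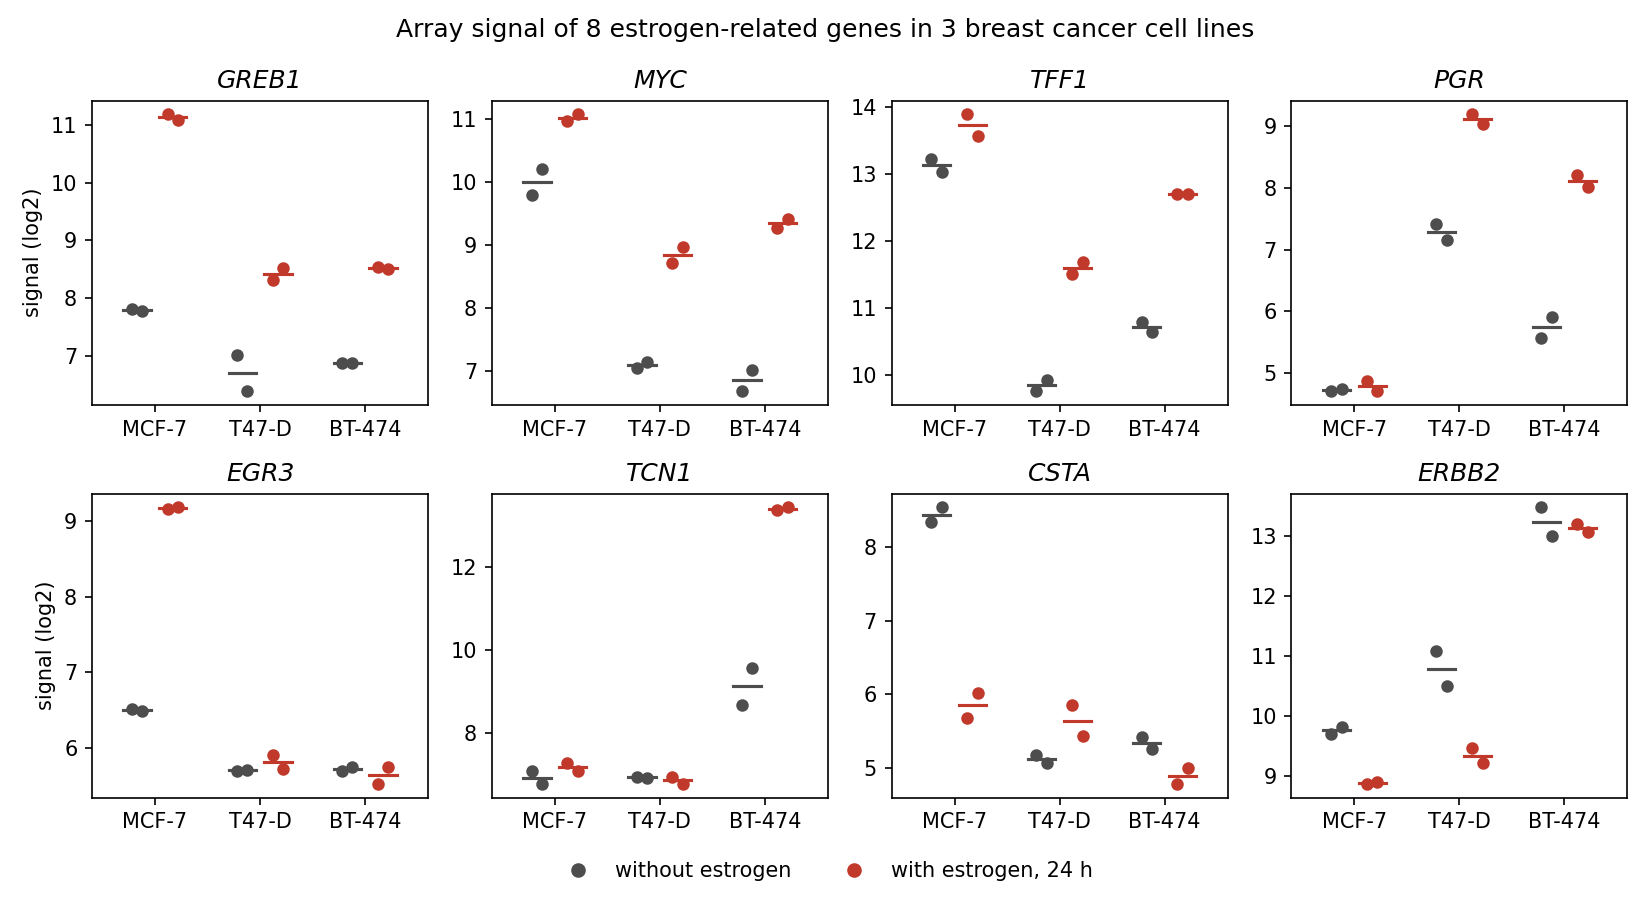
Array signal on the log2 scale (vertical axis) of 8 genes in the 3 cell lines (horizontal axis), each point 1 array and each bar the mean of 2 arrays, without estrogen in grey and with estrogen for 24 h in red. GREB1, MYC and TFF1 were higher with estrogen in all 3 lines, PGR in T47-D and BT-474, EGR3 in MCF-7 and TCN1 in BT-474, while ERBB2 lay near 13.2 in BT-474 in both states.

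In MCF-7 cells, estrogen gave the largest single rises for MYBL1 (3.52 ± 0.16 SE, 11.5-fold) and GREB1 (3.34 ± 0.17, 10.2-fold), whose mean signal went from 7.79 ± 0.03 (SD, n = 2) to 11.14 ± 0.07. The early growth response factor EGR3 rose by 2.67 (6.38-fold) and NPY1R by 2.29 (4.88-fold). The fatty acid-binding protein FABP5 (1.77), the cadherin CELSR2 (1.73), MYB (1.70), ACOX2 (1.58), the protease TMPRSS3 (1.51) and the condensin subunit NCAPG (1.40) completed the 10 largest rises. The protease inhibitor CSTA fell by 2.58 on the log2 scale (5.99-fold), and HOPX (-2.30), the calcineurin regulator RCAN1 (-2.22), VTCN1 (-2.03), RFTN1 (-2.02), EPAS1 (-1.84), BCAS1 (-1.82), H4C8 (-1.65), BLNK (-1.61) and EFNA1 (-1.55) followed. MYC rose by 1.01, TFF1 by 0.60 from an already high signal of 13.13, and ESR1 fell by 0.53 at the brightest of its 6 probe sets, while its other 5 did not pass. PGR did not pass (0.06 ± 0.14, adjusted p = 0.953), and its mean signal of 4.72 without and 4.78 with estrogen lay under 5.78, the mean level below which probe sets were left out, so that a small change would not be seen. A total of 618 probe sets passed limma's test, 277 higher and 341 lower, for 192 genes that rose and 217 that fell.

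Of the 31 classical induced genes 15 rose in MCF-7, 21 adjusted over the list alone, and of the 15 repressed genes 6 fell, 7 adjusted over the list alone, including ERBB2 (-0.88) and CCNG2 (-0.74). DNA replication genes rose in 16 of 39 cases and mitotic genes in 14 of 43, with 33 and 38 adjusted over the list alone, and all 39 and all 43 estimates were positive. One ribosome biogenesis gene, DDX21 (0.71), rose of 23, with 9 adjusted over the list alone. The luminal epithelial list was called downward (5 of 19 fell, 6 adjusted over the list alone, adjusted p = 0.00116), with MUC1 (-0.81), SPDEF (-0.71), CLDN4 (-0.58) and ESR1 among them, and with an adjusted p = 0.0832 with an estimated correlation. The cell cycle brakes, with CITED2 (-1.04) and CCNG2 the 2 that fell of 16 and 5 adjusted over the list alone, were called downward at an adjusted p = 0.000775, and at an adjusted p = 0.241 with an estimated correlation. All 17 interferon response estimates were negative (adjusted p = 0.000775, and an adjusted p = 0.152 with an estimated correlation), and no member passed on its own in limma, with 4 at an unadjusted p below 0.05 and 1 fall adjusted over the list alone. The count of called probe sets was 202 and 212 without MCF-7 control replicates 1 and 2, 179 and 147 without estrogen replicates 1 and 2, 949 without either BT-474 control array, and 1584 when fitted on the 4 MCF-7 arrays alone. The stress and chaperone list was called upward at an adjusted p = 0.0467, and at an adjusted p = 0.211 with an estimated correlation, with ASNS (0.96) up and HERPUD1 (-1.10) down of 18 and 2 rises and 1 fall adjusted over the list alone. Without 1 or more of the MCF-7 arrays MYC, TFF1, ERBB2, ESR1, MUC1, SPDEF and CLDN4 no longer passed (highest adjusted p 0.0861, 0.332, 0.196, 0.265, 0.216, 0.343 and 0.250). The same held for DDX21, CITED2, CCNG2, ASNS and HERPUD1 (0.196, 0.146, 0.142, 0.186 and 0.0971).

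In T47-D cells, OLFM1 rose by 3.32 ± 0.17 SE (9.99-fold), CXCL12 by 2.84 ± 0.14 (7.14-fold), ACOX2 by 2.81 (7.01-fold) and ASNS by 2.27 (4.83-fold). For OLFM1, 1 of the other 2 probe sets passed in the same direction and 1 had the opposite sign. The corticosteroid-binding globulin SERPINA6 (2.08), TEX14 (2.08), SPINK4 (2.02), MYBL1 (1.88), PGR (1.83) and NPY1R (at least 1.80, from a signal under 5.78) completed the 10 largest rises. TFF1 and MYC rose by 1.75 each, GREB1 by 1.73 and CCND1 by 0.74. SERHL2 fell by 1.90 on the log2 scale (3.73-fold), and FGFR4 (-1.81), IL1R1 (-1.51), the fatty acid synthase FASN (-1.47), ERBB2 (-1.45), DDIT4 (-1.36), SOX9 (-1.21), the growth factor pseudoreceptor BAMBI (-1.20), GNMT (-1.17) and VTCN1 (-1.14) followed. A total of 599 probe sets passed limma's test, 456 higher and 143 lower, for 311 genes that rose and 98 that fell. Rises made up 76.1% of these calls, 65.1% (347 higher, 186 lower) after quantile scaling of the arrays and 80.8% (467 higher, 111 lower) after median centring.

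The classical induced list rose in 19 of 31 cases in T47-D, 23 adjusted over the list alone, the glycoprotein hormone STC2 (1.80) among them, and the insulin receptor substrate IRS1 rose by 1.47. Of the repressed genes 4 of 15 fell, 6 adjusted over the list alone. Mitotic genes rose in 17 of 43 cases and DNA replication genes in 11 of 39, with 36 and 23 adjusted over the list alone, MAD2L1 (1.17) among them. Of the ribosome biogenesis genes 6 of 23 rose, 11 adjusted over the list alone, including DDX21 (0.96) and NOP16 (0.91). The stress and chaperone list was called upward (adjusted p = 0.0206, and an adjusted p = 0.152 with an estimated correlation), ASNS being the 1 member of 18 that rose, with 3 adjusted over the list alone. As a reading of RNA integrity, the actin signal at the transcript's 5' end minus that at its 3' end was -0.19 and -1.35 in the control arrays of this line and -1.27 and -2.06 in the estrogen arrays. It was -0.08 to 0.08 in MCF-7 and 0.17 to 0.71 in BT-474. The 2 states of T47-D overlap in it, and also in the GAPDH reading, at -0.28 and -1.32 without and -0.94 and -1.10 with estrogen. With the actin reading as a covariate, an alternative chosen after seeing the data, 156 probe sets passed, and the 4 T47-D arrays alone gave 98. The count was 248 and 295 without control replicates 1 and 2, 207 without estrogen replicate 2, 1074 and 1068 without BT-474 control replicates 1 and 2, and 396 without either MCF-7 estrogen array. Without 1 or more T47-D arrays FGFR4, FASN, CCND1 and NOP16 no longer passed (highest adjusted p 0.162, 0.152, 0.159 and 0.0542), nor did ERBB2, SOX9 and DDX21 on the 4 T47-D arrays alone (0.0515, 0.0541 and 0.0557).

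In BT-474 cells, a line with high ERBB2, estrogen raised the cobalamin-binding protein TCN1 from 9.13 ± 0.63 (SD, n = 2) to 13.40 ± 0.05, a log2 change of 4.28 ± 0.23 SE or 19.4-fold. MYC rose by 2.49 (5.62-fold), PGR by at least 2.37, the pro-apoptotic PMAIP1 by 2.16 (4.47-fold) and TFF1 by 1.98 (3.95-fold). GREB1 (1.65), the growth factor-binding protein IGFBP4 (1.58), MYBL1 (at least 1.58), the lipid phosphatase INPP4B (1.48) and the ubiquitin ligase SIAH2 (1.28) completed the 10 largest rises. The signal of PGR and MYBL1 without estrogen lay under 5.78. RAP1GAP was the 1 named gene that fell, by 0.87 on the log2 scale. ERBB2 (-0.11, adjusted p = 0.918), CCND1 (-0.03, adjusted p = 0.977) and ESR1 (0.35, adjusted p = 0.396) did not pass. A total of 42 probe sets passed limma's test, 39 higher and 3 lower, against 1504 at an unadjusted p below 0.05.

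The classical induced list rose in 8 of 31 cases in BT-474, 17 adjusted over the list alone. No member of the DNA replication, mitosis or ribosome biogenesis lists passed in limma at its brightest probe set, though RFC3 of the first list did at a dimmer one, while 20 of 39, 20 of 43 and 11 of 23 had an unadjusted p below 0.05, and 16, 7 and 8 passed adjusted over the list alone. All 39 DNA replication estimates, 41 of 43 mitotic ones and 21 of 23 ribosome biogenesis ones were positive, with medians of 0.37, 0.30 and 0.29. Camera called the 4 lists upward, at an adjusted p = 1.31e-13 for mitosis, which became an adjusted p = 0.0511 with an estimated correlation, and at or below 0.00597 with an estimated correlation for the other 3. The stress and chaperone list (adjusted p = 0.0225) and the coregulators (adjusted p = 0.0396) were also called upward, with an adjusted p = 0.154 and an adjusted p = 0.400 with an estimated correlation. No member of either passed over all probe sets in limma, with 2 of 18 and 2 of 13 at an unadjusted p below 0.05, and 1 and 0 adjusted over the list alone. The control pair of this line lay farther apart than any other pair, with 2127 probe sets over 0.5 apart against 197 to 959 in the other 5 groups. The count of calls was 653 without control replicate 2 and 34 without control replicate 1, 15 and 14 without estrogen replicates 1 and 2, and 6 on the 4 BT-474 arrays alone. Without 1 or more BT-474 arrays IGFBP4, INPP4B, SIAH2 and RAP1GAP no longer passed (highest adjusted p 0.285, 0.334, 0.208 and 0.173), nor did MYBL1 on the 4 BT-474 arrays alone (0.0707).

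**Figure D2:**
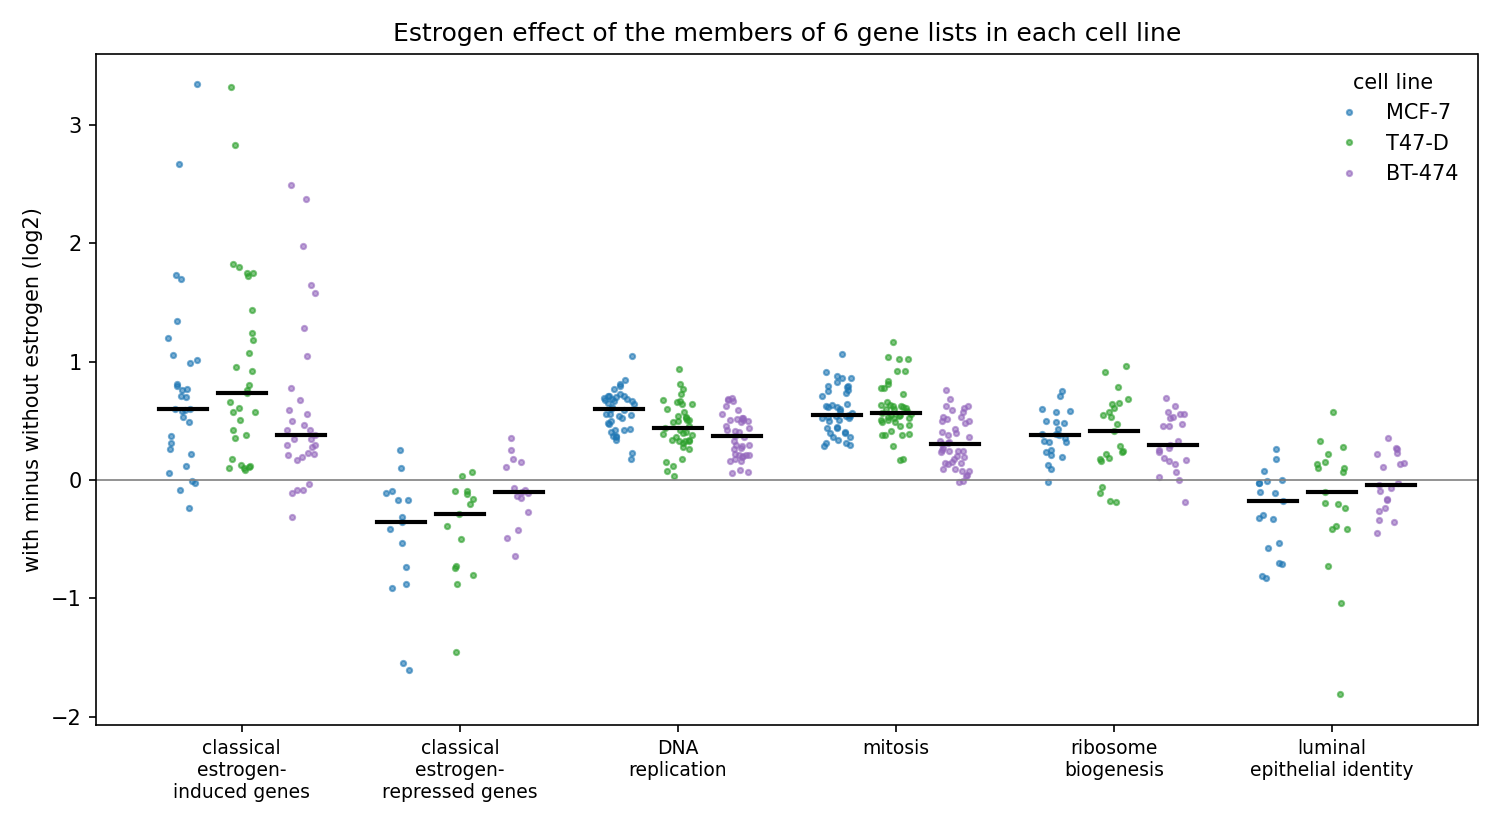
Log2 change with minus without estrogen (vertical axis) of the measured members of 6 gene lists (horizontal axis) in MCF-7, T47-D and BT-474, each point 1 gene and each black bar the median of the list. Medians of the DNA replication list were 0.60, 0.44 and 0.37, and those of the classical repressed list were -0.36, -0.29 and -0.10, in that order of lines.

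The calls of the 3 lines overlapped. MCF-7 and T47-D shared 144 probe sets that rose, against 7.58 for independent lists, and 54 that fell, against 2.93. BT-474 shared 15 rises with MCF-7, against 0.648, and 22 with T47-D, against 1.07. No control array was shared between lines, but the 3 contrasts share the fit's spread of each probe set. The values for independent lists may therefore be too low as a reference. In all, 13 genes rose in all 3 lines: the targets GREB1, TFF1, MYC, RARA, SIAH2, CXCL12 and TPD52L1, and ABCE1, HSPB8, MYBL1, RFC3, TMPRSS3 and TPBG. CXCL12 and RFC3 did so at a dimmer probe set than the one used elsewhere, and no gene passed downward in all 3. Leaving out 1 array at a time kept 4 to 13 of the 13, GREB1, CXCL12, HSPB8 and MYBL1 each time. Without some single arrays RARA, TFF1, TPD52L1 and MYC lost their call in 1 or more lines. ABCE1, SIAH2, TPBG, TMPRSS3 and RFC3 did so more often still. With the actin covariate 7 were kept, and 3 on each line's own 4 arrays. Across probe sets, which are not independent replicates, the effects correlated at 0.476 between MCF-7 and T47-D, 0.411 between T47-D and BT-474 and 0.316 between MCF-7 and BT-474.

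Whether the effect itself differed between lines was tested with limma's moderated F over the interaction terms, and 141 probe sets passed, for 101 genes. EGR3 differed most clearly (adjusted p = 1.02e-05), with a change of 2.67 in MCF-7, 0.11 in T47-D and -0.09 in BT-474. TCN1 changed by 4.28 in BT-474, 4.02 more than in MCF-7 and 4.35 more than in T47-D. SPINK4 rose in MCF-7 and T47-D (1.06 and 2.02) but not in BT-474 (-0.26), and ACOX2 had changes of 1.58, 2.81 and 0.30 in the same order. CSTA fell by 2.58 in MCF-7, while its signal without estrogen was 5.12 in T47-D and 5.34 in BT-474, under the filter level of 5.78, where a fall could not be seen. CXCL12, OLFM1, SERPINA6 and TEX14 rose more in T47-D than in MCF-7, by 2.04, 2.12, 2.26 and 2.13, and more than in BT-474 (adjusted p of the differences 6.81e-05, 0.000325, 0.000939 and 0.0163). PGR rose in T47-D and BT-474 (1.83 and at least 2.37), and its signal in MCF-7 stayed under that level in both states, so the size of the difference from MCF-7 was not measured. For ERBB2, which fell in MCF-7 and T47-D and did not pass in BT-474, the difference itself did not pass limma's moderated F test (adjusted p = 0.0993). The mitosis list moved less in BT-474 than in either other line (adjusted p = 2.94e-06 for both differences, and an adjusted p = 0.375 for both with an estimated correlation), and no single member's difference passed in limma at its brightest probe set, with 12 and 13 of 43 at an unadjusted p below 0.05. The count of 141 was 343 without BT-474 control replicate 2, 69 and 70 without BT-474 estrogen replicates 1 and 2, 68 and 53 without MCF-7 control replicates 1 and 2, 55 and 57 without MCF-7 estrogen replicates 1 and 2, and 78 with the actin covariate.

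Compared with MCF-7 over both estrogen states, BT-474 had far higher signal of GPX1, a peroxide-reducing enzyme (5.49), the dehydrogenase ALDH2 (5.27), CRIP1 (5.09), TOX3 (5.02) and the serine synthesis enzyme PSPH (4.83). TSPYL5 (-5.15), the chloride channel CLIC3 (-5.12), ANP32E (-4.89), TMCO1 (-4.61) and the decoy receptor TNFRSF11B (-4.37) were lowest relative to MCF-7. The 17q12 genes around ERBB2 were higher in 10 of 14 cases in BT-474, and lower in 1, with ERBB2 at 3.88, CDK12 at 3.66, MED1 at 3.54 and PGAP3 at 2.99 (adjusted p = 0.000256, and an adjusted p = 0.127 with an estimated correlation). PGR (at least 2.18, its signal in MCF-7 lying under the filter level of 5.78) and FOXA1 (0.82) were higher in BT-474, and ESR1 (-2.11), MYC (-2.41), GREB1 (-1.77), TFF1 (-1.71), CCND1 (-0.51) and GATA3 (-0.51) lower. Mitotic genes were lower in 33 of 43 cases and higher in 3, with CCNB1 at -2.37. Ribosome biogenesis genes were lower in 14 of 23 and higher in 1 (mitosis and ribosome adjusted p = 6.73e-07 and 0.00183, and an adjusted p = 0.339 and an adjusted p = 0.127 with an estimated correlation). Hypoxia and glycolysis genes were lower in 12 of 19 cases and higher in 3 (adjusted p = 0.0251, and an adjusted p = 0.408 with an estimated correlation). In total 9200 probe sets passed limma's test, 4763 higher and 4437 lower. GATA3 lost its call after quantile scaling (adjusted p = 0.101).

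T47-D differed from MCF-7 most in the secreted protein PIP (6.28), the actin-binding protein CNN3 (5.62), the growth hormone receptor GHR (5.08), CRIP1 (5.04) and GNG11 (4.97), all higher in T47-D. The chemokine receptor ACKR3 (-6.72), LXN (-5.78), TSPYL5 (-5.14), BASP1 (-5.05) and MEST (-4.94) were lower. PGR was higher by at least 3.45, its signal in MCF-7 lying under the filter level of 5.78, ERBB2 by 0.75 and FOXA1 by 0.40, and TFF1 (-2.70), MYC (-2.54), GREB1 (-1.90), CCND1 (-1.86) and ESR1 (-0.41) were lower, while GATA3 did not pass (0.15, adjusted p = 0.129). Interferon response genes were higher in 10 of 17 cases and lower in 2, with BST2 at 2.61 and MX1 at 1.87. Mitotic genes were higher in 29 of 43 and lower in 4 (interferon and mitosis adjusted p = 0.0224 and 0.000434, and an adjusted p = 0.408 for both with an estimated correlation). Lower as lists were hypoxia and glycolysis (11 of 19), ribosome biogenesis (15 of 23) and immediate early genes (9 of 17), with 2, 3 and 3 members higher, at an adjusted p = 0.378, an adjusted p = 0.127 and an adjusted p = 0.408 with an estimated correlation. In total 8932 probe sets passed limma's test, 4765 higher and 4167 lower. ESR1 and ERBB2 lost their call with estrogen only and FOXA1 without estrogen only (adjusted p 0.528, 0.0783 and 0.173), and GATA3 passed after quantile scaling (adjusted p = 0.00151).

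BT-474 against T47-D had higher MARCKS (5.66), BASP1 (5.57), GPX1 (5.49), TOX3 (5.11) and PSPH (5.06), and lower CLIC3 (-5.73), the galectin LGALS1 (-5.01), TMCO1 (-5.00), EFEMP1 (-4.94) and SERPINA6 (-4.82). The 17q12 genes were higher in 11 of 14 cases and lower in 1, with GRB7 at 3.65 and ERBB2 at 3.13. Mitotic genes were lower in 40 of 43 cases, HMMR (-2.52) and NUSAP1 (-2.49) among them, and interferon response genes in 13 of 17, with BST2 at -3.46 and IFITM1 at -2.27. With an estimated correlation these 3 lists had an adjusted p = 0.0953, an adjusted p = 0.127 and an adjusted p = 0.127. DNA replication genes (19 of 39 lower, 8 higher) and the classical repressed list (8 of 15 higher, 3 lower) passed narrowly, at an adjusted p = 0.0498 and 0.0340, and at an adjusted p = 0.408 for both with an estimated correlation. CCND1 (1.35), TFF1 (0.99) and FOXA1 (0.42) were higher in BT-474, ESR1 (-1.70), PGR (-1.28) and GATA3 (-0.67) lower, and MYC (0.13, adjusted p = 0.428) and GREB1 (0.13, adjusted p = 0.438) did not pass. In total 7513 probe sets passed limma's test, 3590 higher and 3923 lower. With estrogen only FOXA1 lost its call (adjusted p = 0.0702) and MYC passed (adjusted p = 0.0369), as GREB1 did without T47-D control replicate 1 (adjusted p = 0.0358). Several of the largest differences in the 3 line comparisons, among them TOX3, PSPH, GPX1 and TSPYL5, set a bright signal against one under 5.78 and are lower bounds. In all 3 line comparisons the lists' counts hold 1 line per side, and the MCF-7 arrays carry titles of another form than the rest and higher ribosomal control signals, with 28S at 8.82 to 9.49 against 5.23 to 5.60. The T47-D arrays lie apart in the actin reading of RNA integrity, which was not used as a covariate here. Line cannot be told apart from array handling for MCF-7. The T47-D control arrays, at -0.19 and -1.35 in the actin reading, had 79 probe sets over 1 apart on the log2 scale. Against MCF-7, 1063 called probe sets were higher and 1028 lower by over 2-fold in T47-D. This argues against RNA integrity as the source of most of these large differences. For other differences of T47-D, line cannot be told apart from RNA integrity.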

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

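The slope of the BT-474 response, the estrogen activity of its control array and the integrity correlations from single controls were tests chosen only after the result was seen. The estrogen effect differed between lines at 141 probe sets by the moderated F test of limma, and the named genes among them follow with their adjusted F p. The differences were clearest for EGR3 (1.02e-05), TCN1 (7.84e-05), SPINK4 (8.56e-05), CSTA (8.56e-05), CXCL12 (0.000113), ACOX2 (0.000197), TEX14 (0.000242), PGR (0.000308), SERPINA6 (0.000373), OLFM1 (0.000429) and RCAN1 (0.000446). Next came SERHL2 (0.00162), CELSR2 (0.00187), MYBL1 (0.00187), EPAS1 (0.00228), RFTN1 (0.00347), BLNK (0.00548), FABP5 (0.00548), NPY1R (0.00560), GREB1 (0.00751), TFF1 (0.00808) and H4C8 (0.00952). The remaining ones were HOPX (0.0118), PMAIP1 (0.0133), MYB (0.0216), VTCN1 (0.0230), EFNA1 (0.0243), NCAPG (0.0259), ST6GAL1 (0.0268), MYC (0.0284), BCAS1 (0.0325), IL1R1 (0.0333), DDIT4 (0.0356) and ASNS (0.0389). The differences of CSTA and PGR set lines against others where the signal lay under 5.78, so their size was not measured.

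Gene lists whose effect differed between lines by camera were, for BT-474 minus MCF-7, mitosis (adjusted p = 2.94e-06, lower), the classical repressed genes (5.92e-05, higher), DNA replication (0.000145, lower), cell cycle brakes and quiescence (0.000637, higher), hypoxia and glycolysis (0.00333, lower) and luminal epithelial identity (0.00788, higher). For BT-474 minus T47-D they were mitosis (2.94e-06, lower), the classical induced genes (0.000283, lower) and the classical repressed genes (0.000287, higher), and for T47-D minus MCF-7 DNA replication (0.0267, lower). None of these passed with an estimated correlation, where the adjusted p lay between 0.209 and 0.382.

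BT-474 had 42 calls against 618 in MCF-7 and 599 in T47-D, its 2 control arrays lie far apart, and leaving out control replicate 2 gave 653 calls while leaving out control replicate 1 gave 34, so an atypical control array could account for the low count, though which of the 2 is atypical stays open, since a lone control's own deviation counts as effect. The line's own 4 arrays gave 6 calls, against 1584 for MCF-7 on its own 4. This met the bound set beforehand against the shared spread of the fit hiding BT-474 effects. However, such a fit leaves few degrees of freedom and still holds the wide control pair, and T47-D also dropped, to 98 calls. The count therefore does not decide. Estrogen activity in control replicate 2 stays open: the median effects against replicates 1 and 2 were 0.51 and 0.32 over the classical induced list and 0.47 and 0.19 over mitosis (0.61 and 0.52 in MCF-7), replicate 2 lay between the states on the third component, and its difference from replicate 1 correlated at 0.312 with the line's own effect over all probe sets, which a deviating replicate 1 would also give, as both values hold the control arrays. Against it, that difference had a median of 0.0532 over the induced list (interquartile range 0.305), was mostly positive for the repressed genes (10 of 15) and the brakes (12 of 16) too, and correlated at 0.0644 with the effects in the other lines. Over the probe sets called in MCF-7 the slope of the BT-474 effects was 0.232, against 0.485 for T47-D. Over those called in T47-D it was 0.293 against 0.503 for MCF-7. From pairs of single arrays it was 0.228 to 0.235 against 0.473 to 0.498, and 0.256 to 0.330 against 0.461 to 0.545. The response at these probe sets was thus smaller in BT-474 with either control, which argues against 1 atypical control array as the source of the smaller slope. How much of the low count of calls comes from the smaller response and how much from the control array was not tested.

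In T47-D 76.1% of the calls were rises. RNA integrity stays open. Across the calls the estrogen effect correlated at -0.0271 with the difference between the 2 control arrays, which differ in the actin reading. This met the bound set beforehand for no part in it, but both values hold those arrays. With the effect taken from control 1 or control 2 alone the correlation was 0.125 and -0.178. The shared array pushes the first up and the second down, so these 2 values do not decide. Over all probe sets the correlation with the effect from both controls was 0.102. With the actin covariate 156 probe sets passed, 71.2% of them rises, and 140 of the 156 were among the 599 calls. Array scaling cannot be told apart from a true excess of rises, because quantile scaling left 65.1% rises, between the bounds set for either reading, and median centring went the other way, to 80.8%. No biological explanation was tested for this pattern.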

How the results depend on the processing

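The actin covariate was the alternative chosen only after the result was seen. Of 429 named results, 335 kept their direction and their side of the threshold under every alternative, and of 7396 alternative values 343 lost the call, 9 gained it and 1 reversed. CXCL12 in BT-474 against T47-D was 0.0809 (adjusted p = 0.719) without estrogen only, against -1.15 over both states, since estrogen raised it in T47-D. Fitted on each line's own 4 arrays, which leaves few degrees of freedom, MCF-7 had 1584 calls, T47-D 98 and BT-474 6. With the actin covariate T47-D had 156 calls and the difference between lines 78, and the cause was not tested. The average had 672 calls leaving out MCF-7, 647 leaving out T47-D and 1455 leaving out BT-474. Leaving out each array in turn gave 147 to 949 calls in MCF-7, 207 to 1074 in T47-D, 14 to 653 in BT-474, 896 to 2429 for the average and 53 to 343 for the difference. Of the list tests 18 passed with an estimated correlation, against 28. The line comparisons stayed within 1.5 times under every alternative run on them, which leaves out the block and the covariate. With the replicate block, MCF-7 had 697 calls, T47-D 748, BT-474 52, the average 1819 and the difference 134. The labels do not say whether equal replicate numbers mark arrays handled together, so the numbers were not taken as pairs in the main fit. Replicate differences of the 2 estrogen states correlated at 0.460 in MCF-7, 0.165 in T47-D and 0.0988 in BT-474. A link between equally numbered arrays is thus not excluded, least of all in MCF-7. Signal near background limits dim genes: without a filter the average had 1627 calls, and 1426 with the lowest 50 percent left out. The pseudocount alternatives were not run, since the values are log2.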

Other observations

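The histone and amino acid lists were chosen only after the result was seen, and so was the reading of the histone probe sets as undecided. Genes of amino acid synthesis and transfer RNA charging rose with estrogen beside ASNS. Of 23 measured genes 14 rose on average (camera adjusted p = 1.84e-15, and an adjusted p = 0.00655 with an estimated correlation), and none fell. The synthetases GARS1 (0.73), IARS1 (0.71), YARS1 (0.68) and TARS1 (0.62), which charge transfer RNAs, the amino acid transporter SLC7A5 (0.63) and the folate and serine enzymes MTHFD2 (0.51), SHMT2 (0.48) and PHGDH (0.45) were among them. In T47-D 11 of the 23 rose, GARS1 by 1.21, YARS1 by 1.07 and SHMT2 by 1.02, in MCF-7 3 rose (ASNS, YARS1 and PHGDH), and in BT-474 SLC7A5 rose by 0.91.

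Some histone transcripts fell with estrogen while DNA replication genes rose. Of 28 histone genes 8 fell on average and none rose (adjusted p = 6.68e-06, and an adjusted p = 0.0172 with an estimated correlation). In MCF-7 9 fell (adjusted p = 0.00655 with an estimated correlation), in T47-D 3 (median -0.05, adjusted p = 0.157 with an estimated correlation) and in BT-474 none in limma, with 5 at an unadjusted p below 0.05 (median -0.12, adjusted p = 0.0679 with an estimated correlation). Histone probe sets whose names do not mark them as designed for 1 transcript had a median average effect of -0.34 (11 probe sets). Whether these match several genes was not tested by sequence. The 18 named as designed for 1 transcript had a median of -0.0293, which met the bound set for cross-hybridisation between histone genes. Of 10000 random sets of like brightness, 5319 had a median at or below it, so as a group the 18 showed no fall beyond such sets. However, H1-2 (-0.36) and H2AC8 (-0.47), the 2 of the 18 that fell on average, count against cross-hybridisation as the whole source. Both were called downward in MCF-7 but not in T47-D or BT-474. The single-transcript sets are also dimmer (median level 6.66 against 8.32), so the test does not decide. An exit from quiescence as the link to DNA replication could not be tested, since 3 lines allow a one-sided rank p of 0.167 at best.

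Neither the regroupings of arrays within lines nor the splits for the line differences can test chance here. For the average, 1 of 100 regroupings within lines, the real one, gave as many calls (1558, highest other 728). For BT-474 against MCF-7, T47-D against MCF-7 and BT-474 against T47-D, 1 of 35 splits of the 8 arrays, the real one, gave as many (8719, 8215 and 6515, highest others 1, 2 and 2). A mixed split puts the line differences into the spread. Most regroupings within lines mix the estrogen states in 1 or more lines and put the estrogen effect there (median of the other regroupings 1 call). Few calls were thus bound to result in both, and no conclusion is drawn. Nor do these splits part line from array handling in MCF-7 or from RNA integrity in T47-D, for which the replicate values given with the line comparisons are the evidence.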
